A study of Mus musculus with 337 samples.

How the data were processed

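The data were single-cell RNA profiles of mouse bone marrow progenitors captured on the Fluidigm C1 and sequenced with paired ends, per the labels. Expression was estimated with RSEM on the mouse build mm10, per the submitters' processing notes. The version of RSEM, the aligner, the gene annotation and any filter on cells were not given in the sources used here. The deposited table held log2 values of TPM + 1. The unit was read from the values: turned back to TPM, each cell summed to between 976676 and 1000000, and 100% of the values from 0 to 1000 TPM were multiples of 0.01 TPM within a tolerance of 0.02 steps. TPM is scaled to a fixed total per cell and keeps no depth, so a gene that takes much of a cell's TPM lowers the others. A value of 0 can be a transcript that was missed or an estimate that gave the reads to another gene. The table had 14415 genes, of which 503 were listed at 0 in every cell, and 337 cells. No mitochondrial genes with mt- names were in the table. No column was left unused.

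Each column was matched to its sample by the name in the sample's description, and each sample to its gate by its title. The 7 gates held 37 to 68 cells. Both CLP gates shared a date-like start of the name, as did both MultiLin gates, but each of the 7 gates had a full name prefix of its own, so capture and gate cannot be told apart in any comparison. No animal or culture was named, so each gate counted as 1 sample, and no test, p-value or count of changed genes was made from cells. Gene names were matched to a reference table of the GRCm38 assembly, the assembly called mm10: 13508 matched a symbol and 841 matched only a synonym. Coordinates come from that table, and the positions given are those of protein-coding genes.

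For each of 5 comparisons, the difference in mean log2(TPM + 1) over cells was computed with SDs over cells. For LSK DNDP the second side was the mean of the 6 other gate means, each with equal weight. A gene counted as detected at 1 TPM or more. Shares of cells have exact Clopper-Pearson intervals at 95%, and a share of 0 has the upper limit that 3 counts would give. The pseudocount of 1 compresses differences of low genes. The depth of a cell was unknown, so the precision of a single value was unknown, and the number of genes at 1 TPM or more served as a measure of complexity.

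The gate genes, gene lists, co-detection pairs, comparisons and the rule for named genes were fixed before the data were examined. Named genes reached 1 TPM in at least 30% of the cells of the higher gate; the 10 with the highest and the 10 with the lowest difference were named per comparison, and the 5 highest per gate against the mean of the others. Predicted or unnamed genes, histone, cytosolic ribosomal protein, small RNA and mitochondrially encoded genes were left out. Predicted or unnamed genes were recognised by fixed forms of the symbol. These forms did not cover AW112010, a long noncoding RNA gene, which was kept. Mitochondrial ribosomal proteins encoded in the nucleus, such as Mrps14, were kept, a reading of the rule made when it was applied. From each list the members with the largest differences, up to 4, could be named. Some genes that the rule names are not reported here. The co-detection counts at 10 TPM are an alternative fixed beforehand.

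The 15 lists were stem, early lymphoid, B lineage, T and innate lymphoid, dendritic, erythroid, megakaryocyte, basophil with mast and eosinophil, neutrophil, monocyte, S phase, G2 and M phase, immediate early and stress, interferon response and housekeeping genes. Gate genes were left out of the lists, and Cd3e, Cd3g, Cd209d, Hba-a2, Hbb-bs, Gp6, Mpig6b, Cma1 and Tpsb2 had no matching name in the table. A list score is the mean log2(TPM + 1) of its measured members in a cell. Members count as higher or lower at a difference of at least 0.5. The median member difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists share members: Irf7, for example, is on the dendritic and interferon response lists.

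Markers of other cell types were counted as well. The T cell marker Cd3d was found in 21 of 337 cells, the B cell markers Ms4a1 in 2 and Cd22 in 8, the macrophage markers C1qa in 6 and C1qb in 10, the mature neutrophil markers Retnlg in 6, Mmp8 in 6 and Mmp9 in 0, the erythroblast markers Hba-a1 in 31 and Alas2 in 8, the plasma cell markers Mzb1 in 22 and Sdc1 in 35, and the stromal markers Col1a1 in 0, Pecam1 in 86 and Lepr in 285. S100a8 was found in 98 and S100a9 in 84 cells, Cxcr2 in 332, Xbp1 in 102, Fcer2a in 19 and Hbb-bt in 40. Markers without a matching name in the table, among them Cd3e, Cd3g, Trbc2, Jchain, Adgre1, Cxcl12, Cdh5 and the 3 of mast cells, were not analysed here.

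The calculation was tested on simulated data. LSK DNDP cells were split at random into 2 parts of 34 cells, and 200 genes of 14415 were shifted by 1, 2 or 4 on the log2 scale in one part. Of 3175 eligible genes, the shifted ones were recovered with median differences of 1.17, 2.26 and 4.16, where the other eligible genes had a median of 0.19, 0.18 and 0.19. Of the shifted genes, 31.5%, 71% and 97.5% were among the 200 highest. Lists of 15 shifted genes lay above percentile 97.5 in 98%, 100% and 100% of cases. Of 200 random lists without a shift, 6%, 3% and 5% lay outside the central 95%. The shift was added to every cell of the shifted part, zeros included, and all simulated lists were drawn from eligible genes. These rates may therefore not hold for the real lists, which also had members found in few cells.

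Alternatives fixed beforehand were pseudocounts of 0.1 and 10, log2 ratios of mean TPM, cells within the shared range of detected genes, cells with at least 1000 such genes, rescaling to the upper quartile, leaving out the 3 highest cells per gate, other reference gates, other detection thresholds and other filters on low values. Added after seeing the data were the removal of cells in which 50 genes held over 40% or over 90% of the TPM, and matching of cells on genes listed above 0. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No clustering was done, and no cell was given a type. Of the genes that reached the table, 16 shared identical values in every cell with another gene, and Hbb-bt and Hbb-b2 differed by at most 0.01 on the log2 scale, so members of such families are uncertain.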

Results

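Single cells from mouse bone marrow, wild type and untreated per the labels, were captured on the Fluidigm C1, a microfluidic device that isolates individual cells for full-length RNA sequencing. The table held 337 cells and 14415 genes. The cells came from 7 sort gates of blood progenitors. The LSK DNDP gate (68 cells) pooled CD48-CD150- and CD48+CD150+ cells of the LSK compartment, the lineage-negative Sca1+ Kit+ fraction that contains the stem cells. In the MultiLin population, sorted on a Gata1-mCherry reporter, 50 cells were labelled negative CD150+ and 37 cells intermediate-high. The LK gate, from lineage-negative Kit+ cells, held 42 cells labelled Gfi1-tdTomato intermediate Csf1r-. The labels of the other gates name no reporter, so the mouse line may have differed between gates. The lymphoid gates were cKit+CD127+ (47 cells), CLP Ly6D- (56 cells) and CLP Ly6D+ (37 cells), where CLP stands for common lymphoid progenitor.

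The deposited values were log2(TPM + 1), where TPM is the abundance of transcripts scaled to a fixed total per cell. TPM keeps no read depth, so the depth of each cell was unknown. A median of 2655 genes per cell reached 1 TPM, with a range of 276 to 5468. The median was highest, at 3322 genes, in the gate labelled negative CD150+ and lowest, at 2343, in the CLP Ly6D- gate. Zeros made up 75.5% of the table. Each cell was a separate GEO sample and no animal or culture was named, so each gate counted as 1 sample and no test between gates was made. Differences below are given as first gate minus second gate in mean log2(TPM + 1), with SDs over cells. Shares are of cells at 1 TPM or more, with exact Clopper-Pearson 95% intervals that cover counting error only. The percentile of a list's median member is its place among 10000 random lists matched on mean expression, as a description of these libraries.

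The genes behind the gates were examined first, as a check of the labels. Kit, the stem cell factor receptor, was found in 80.9% of LSK DNDP cells (69.5 to 89.4%) and 21.6% of CLP Ly6D+ cells (9.83 to 38.2%). Ly6a, which encodes Sca1, was found in 42 of 68 LSK DNDP cells and in 0 of 50 and 0 of 37 cells of the MultiLin gates, which allows Ly6a shares of up to 6% and 8.11%. Il7r, which encodes CD127, was found in 27 of 47 cKit+CD127+ cells, 35 of 56 CLP Ly6D- cells and 28 of 37 CLP Ly6D+ cells, and in 0 cells of the LSK DNDP, MultiLin and LK gates, which allows an Il7r share of up to 4.41%, 6%, 8.11% and 7.14% in these 4 gates. Flt3, which encodes CD135, was found in 91.1% of CLP Ly6D- cells (80.4 to 97%) and 94.6% of CLP Ly6D+ cells (81.8 to 99.3%). Slamf1, which encodes CD150, was found in 4 of 68 LSK DNDP cells and 2 of 50 cells of the gate labelled negative CD150+. Gfi1 was found in 1 of 42 cells and Csf1r in 3 of 42 cells of the gate labelled Gfi1-tdTomato intermediate. Gfi1 was also found in 8 of 68 LSK DNDP, 4 of 47 cKit+CD127+, 3 of 56 CLP Ly6D- and 3 of 37 CLP Ly6D+ cells. In the MultiLin gates it was found in 4 of 37 cells labelled intermediate-high and 0 of 50 labelled negative CD150+. Its messenger RNA thus did not set the Gfi1 reporter gate apart. The remaining gate genes, Cd48, Cd34, Fcgr3 and Ptprc, ranged widely: Cd48 was found in 42.6% of LSK DNDP cells, Cd34 in 42% of cells of the gate labelled negative CD150+, Fcgr3 in 37.8% of the gate labelled intermediate-high, and Ptprc in 67.6% of LSK DNDP cells.

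Mean Gata1 messenger RNA ran opposite to the order of the reporter labels, which name a sorted reporter and not the messenger RNA. Gata1 (chromosome X, 7959260 to 7976663, GRCm38, the assembly called mm10), the transcription factor of erythroid and megakaryocytic development, averaged 2.20 ± 3.38 in the gate labelled intermediate-high and 3.91 ± 3.68 in the gate labelled negative CD150+. It was found in 14 of 37 cells (37.8%, 22.5 to 55.2%) and 31 of 50 cells (62%, 47.2 to 75.3%), and the intervals overlapped. At 10 TPM or more the Gata1 shares were 24.3% and 50%. These 2 gates, and the Gfi1 reporter gate, are therefore named below by their labels alone.

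**Figure D1:**
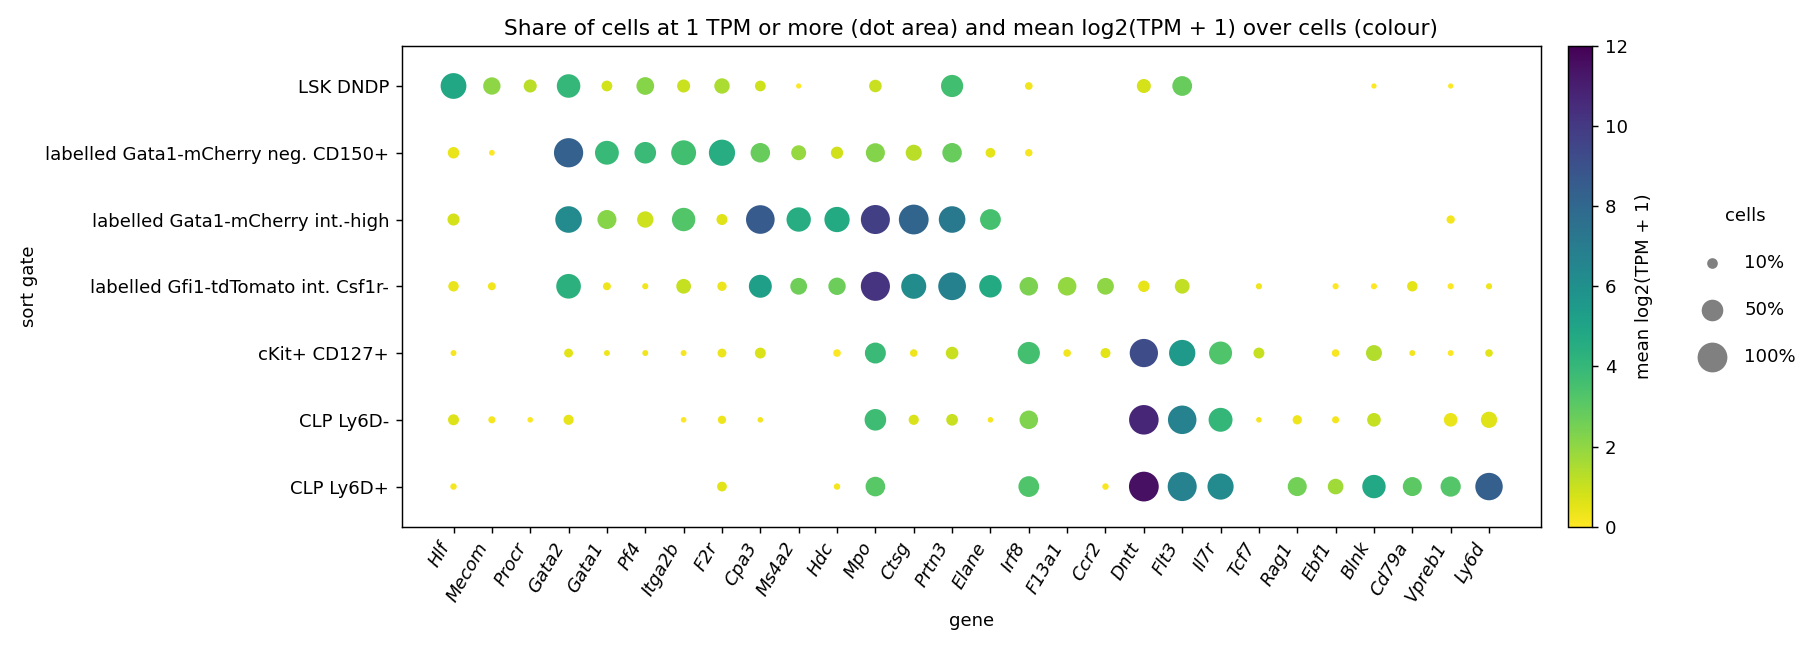
Dot area shows the share of cells at 1 TPM or more and colour the mean log2(TPM + 1) over cells, for lineage genes (columns) in the 7 gates (rows). Hlf was found in 73.5% of LSK DNDP cells, Mpo in 94.6% of cells of the gate labelled intermediate-high, and Ly6d in 83.8% of CLP Ly6D+ cells.

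The CLP gates differed in Ly6D, a surface protein used to separate lymphoid progenitors by their bias to the B lineage, and their comparison asked which genes went with it. Ly6d itself (chromosome 15, 74762056 to 74763567) averaged 8.43 ± 4.57 in CLP Ly6D+ cells and 0.60 ± 1.21 in CLP Ly6D- cells, and was found in 31 of 37 and 15 of 56 cells. Of the B lineage genes, 9 of 17 were higher in CLP Ly6D+ cells by at least 0.5, the bound used for all list counts below. Blnk (chromosome 19, 40928927 to 40994221), an adaptor of B cell receptor signalling, was higher by 3.76 and was found in 59.5% against 17.9% of cells. Cd79a (chromosome 7, 24897497 to 24901858), a signalling chain of the receptor, was higher by 2.92 and was found in 14 of 37 against 0 of 56 cells, which allows a Cd79a share of up to 5.36%. Vpreb1, part of the surrogate light chain, was higher by 2.81 and was found in 43.2% against 17.9% of cells, or 35.1% against 3.57% at 10 TPM. Rag1, the recombinase of receptor gene segments, was found in 37.8% (22.5 to 55.2%) against 7.14% (1.98 to 17.3%) of cells.

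The other genes highest above the Ly6D- gate were Sdc4 (3.24), a heparan sulfate proteoglycan, Pgls (3.22), Atp1b3 (3.20), Myl4 (3.18), Ly6e (2.61) and Mzb1 (2.56), a chaperone of antibody assembly. Mzb1 was also on the fixed list of plasma cell markers, and was found in 40.5% of CLP Ly6D+ cells. The genes lowest in CLP Ly6D+ cells were Wfdc17 (-3.20), Car2 (-2.59), a carbonic anhydrase, Rgs18 (-2.48), Lmo2 (-2.28), a transcriptional cofactor of blood stem cells, Tcp1 (-2.21), Mrps14 (-2.17), Il1r1 (-2.14), a receptor of interleukin 1, Ngdn (-2.13), Smc4 (-2.09) and Eltd1 (-2.04). Of the B lineage list, 8 of 17 members lay within 0.5 and 0 were lower. The list score was 1.78 ± 1.53 in CLP Ly6D+ and 0.61 ± 0.35 in CLP Ly6D- cells, and the median member lay at percentile 100. On the early lymphoid list 7 of 12 members were higher, among them Rag1 (2.22), Lax1 (1.56) and Ikzf1 (1.13), and 1 was lower. Its score was 4.33 ± 0.88 against 3.61 ± 1.09, at percentile 99.9.

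Other lists differed less between the CLP gates. Of 15 immediate early and stress genes, 9 were lower in CLP Ly6D+ cells and 1 higher, with Ier3 (-1.61), Egr1 (-1.31), Nr4a1 (-1.19) and Fos (-1.05) leading, and the score difference was -0.58. The S phase list was higher by 0.37 (6 of 15 higher, 0 lower) and the G2 and M phase list lower, at -0.28 (0 higher, 4 lower). Monocyte genes went both ways, with 4 of 15 higher, including Tifab (2.03), Ly86 and Irf8 (1.00), and 3 lower (0.27). Stem (-0.31), neutrophil (-0.19), erythroid (-0.16), dendritic (-0.15), T and innate lymphoid (-0.15), interferon response (-0.10), megakaryocyte (-0.09), basophil, mast and eosinophil (-0.01) and housekeeping (0.12) scores lay within 0.5. The names of the CLP cells shared a start but had a different number per gate, so capture and gate cannot be told apart. The B lineage difference of 1.17 became 3.49 as the log2 ratio of mean TPM, and in cells matched on detected genes the S phase and the G2 and M phase differences became 0.61 and -0.12.

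The MultiLin gates were labelled by different levels of a Gata1 reporter, and their comparison asked what went with that level. The negative gate was also labelled CD150+, while the other label names no CD150, so that marker cannot be told apart from the reporter level. The direction is drawn from labels whose order mean Gata1 messenger RNA did not follow. Most genes of the neutrophil list were higher in the gate labelled intermediate-high. Mpo (chromosome 11, 87793784 to 87804412), myeloperoxidase, averaged 9.78 ± 3.69 against 2.22 ± 3.54 in the gate labelled negative CD150+ and was found in 94.6% against 38% of cells, or 89.2% against 16% at 10 TPM. Ctsg (chromosome 14, 56099885 to 56102574), cathepsin G, was higher by 6.89 and was found in 37 of 37 against 13 of 50 cells, or 31 against 5 at 10 TPM. Cpa3 (chromosome 3, 20215616 to 20242209), a protease of mast cells and basophils, was higher by 5.82. Megakaryocyte genes were lower: F2r, the thrombin receptor, differed by -3.92, Fli1 by -3.02, Pf4 (chromosome 5, 90772435 to 90773383), platelet factor 4, by -2.91 and Cd9 by -2.87.

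Rab44 (4.59), Prtn3 (4.35), a granule protease, Lmo4 (4.10), Hdc (3.86), which makes histamine, Lcp1 (3.65), Csf2rb (3.43), a receptor chain of myeloid cytokines, and Tyrobp (3.24) completed the highest genes of the gate labelled intermediate-high. The lowest were Eno1 (-5.62), Kars (-4.78), Poldip3 (-4.68), Hsd17b10 (-4.43), Dpysl2 (-4.39), Car2 (-4.29), Tagap1 (-4.25), Mfsd2b (-4.16), Adam10 (-4.09) and Fam212a (-4.04). Eno1, enolase, has a near copy, Eno1b, in the table and is uncertain; summed, the pair averaged 5.42 ± 4.05 in the gate labelled intermediate-high and 8.31 ± 3.28 in the gate labelled negative CD150+.

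Of 19 neutrophil genes, 14 were higher in the gate labelled intermediate-high and 0 lower, with scores of 2.79 ± 1.22 against 0.99 ± 0.99 and the median member at percentile 100. Of 13 basophil, mast and eosinophil genes, 6 were higher and 1, Gata2 (-2.04), lower, with a score difference of 1.09 and the median member at percentile 100. Of 17 megakaryocyte genes, 12 were lower and 0 higher, with scores of 0.92 ± 0.59 against 2.60 ± 1.38 and the median member at percentile 0. On the erythroid list 8 of 18 were lower and 0 higher (-0.66), including Blvrb (-2.23) and Icam4 (-2.04). Immediate early and stress genes were higher, with 12 of 15 higher, 0 lower and a difference of 1.70, led by Fos (3.10), Dusp1 (2.93), Junb (2.84) and Fosb (2.84). Monocyte genes differed by 0.54 (4 of 15 higher), stem genes by -0.54 (6 of 18 lower, 1 higher), interferon response by -0.21, early lymphoid by 0.20, T and innate lymphoid by -0.08, dendritic by 0.02 and B lineage by -0.01.

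The S phase (-1.04, 13 of 15 lower), G2 and M phase (-0.84, 10 of 15 lower) and housekeeping (-0.85, 6 of 9 lower) lists were also lower in the gate labelled intermediate-high, which had fewer genes at 1 TPM or more (a median of 2638 against 3322). Their median members lay at percentiles 19.2, 8.66 and 33.7. Among the 18 and 24 cells of these gates with 2509 to 3389 such genes, the 3 differences were -0.04, -0.08 and -0.29, the stem difference was -0.32 and the megakaryocyte difference was -1.06. In cells matched on genes listed above 0, a matching chosen after the results were seen, the G2 and M phase difference turned to 0.15, while the other 2 stayed below 0. As log2 ratios of mean TPM, the megakaryocyte difference of -1.68 became -2.95. Capture and gate cannot be told apart here.

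**Figure D2:**
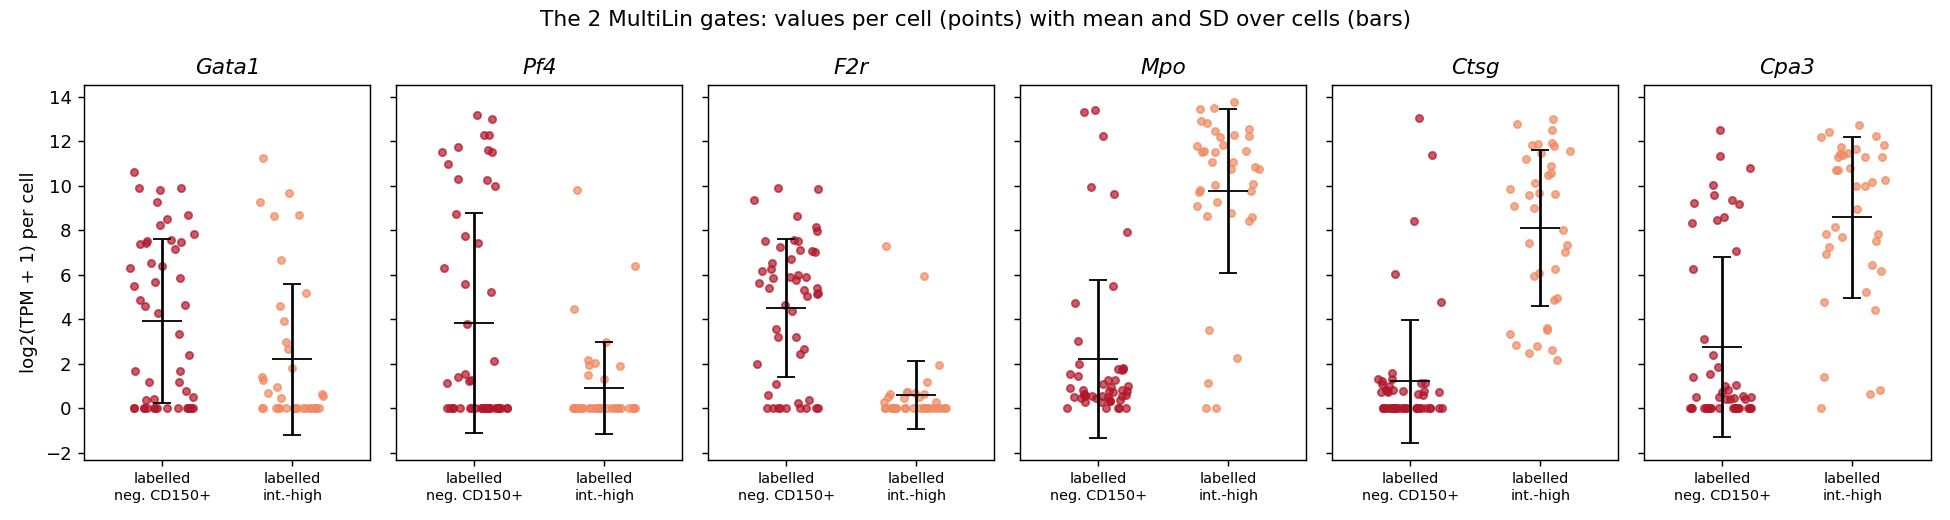
Each point is the log2(TPM + 1) value of 1 cell of the gates labelled negative CD150+ (50 cells) and intermediate-high (37 cells), for 6 genes, with the mean and the SD over cells as bars. Gata1, Pf4 and F2r were lower, and Mpo, Ctsg and Cpa3 higher, in the gate labelled intermediate-high.

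The cKit+CD127+ gate shared Kit and the interleukin 7 receptor with the CLP Ly6D- gate, which was further set by lineage markers, Sca1, CD135 and Ly6D, so that the comparison asked what the wider gate held. Genes of the interferon response were higher in cKit+CD127+ cells. Irf7 (chromosome 7, 141263183 to 141266499), a master regulator of type I interferon, was higher by 1.47 and was found in 34% (20.9 to 49.3%) against 16.1% (7.62 to 28.3%) of cells. Rtp4 (1.43), Oas1a (1.35) and Usp18 (1.34), all induced by interferon, followed. Of the T and innate lymphoid genes a minority was higher, among them Id2 (1.49), Rora (0.97), Zbtb16 (0.53) and Tcf7 (0.83), the last found in 5 of 47 against 1 of 56 cells. That list's difference of 0.33 became 0.13 without the 3 highest cells of each gate, and 1.30 as the log2 ratio of mean TPM. Il12a (chromosome 3, 68690644 to 68698550), a subunit of interleukins 12 and 35, was the lowest, at -3.11, with 6.24 ± 4.26 against 9.35 ± 2.54.

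The highest genes were Aldoa (3.18), an enzyme of glycolysis, Edf1 (2.89), Snrpb (2.70), Prr13 (2.69), Cox5a (2.59), a subunit of the respiratory chain, AW112010 (2.49), Fam173a (2.48), Tmbim6 (2.47), Msn (2.42) and Hmga1 (2.42). After Il12a, the lowest were Gnas (-2.59), H2-Ob (-2.32), Cox6a2 (-2.30), Srsf6 (-2.22), Fosb (-2.04), Pbk (-1.97), Hnrnpab (-1.95), Cdk19 (-1.95) and Sh3bgrl (-1.93). Of 13 interferon response genes 8 were higher and 0 lower, with a score difference of 0.72 and the median member at percentile 100. Of 14 T and innate lymphoid genes 5 were higher and 0 lower, with a score difference of 0.33 and the median member at percentile 97.1. Of 15 G2 and M phase genes 9 were lower and 0 higher (-0.50), among them Cdk1 (-0.99), Ccnb2 (-0.98) and Top2a (-0.91). Immediate early and stress genes differed by -0.50 (6 of 15 lower, 2 higher). Early lymphoid genes differed by 0.14 in the mean score and -0.07 in the median member, so that their signs differed. The erythroid (0.31), dendritic (0.26), monocyte (0.24), housekeeping (0.19), megakaryocyte (0.14), basophil, mast and eosinophil (0.05), stem (0.02), B lineage (0.01), neutrophil (0.01) and S phase (-0.02) scores lay within 0.5.

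Hemoglobin transcripts were found in several gates. In 1 cKit+CD127+ cell, cell 76, Hba-a1 took 52.9% of the TPM, 50 genes took 98.3%, and 276 genes reached 1 TPM. Of the other 46 cKit+CD127+ cells, 10 held Hba-a1, against 0 of 56 and 0 of 37 cells of the CLP gates, 12 of 42 cells of the gate labelled Gfi1-tdTomato intermediate and 4 of 68 LSK DNDP cells. In the MultiLin gates, 2 of 50 cells labelled negative CD150+ and 2 of 37 labelled intermediate-high held Hba-a1. Hbb-bt was found in 23.4% of cKit+CD127+ cells, 20.6% of LSK DNDP cells and 19.0% of the gate labelled Gfi1-tdTomato intermediate. Its shares were lower in the remaining gates. Without cell 76 the erythroid difference was 0.20, and as the log2 ratio of mean TPM over all cells it was 2.87. In cells matched on detected genes the G2 and M phase difference was -0.92. The name prefixes of these gates differed, so capture and gate cannot be told apart.

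The gate labelled Gfi1-tdTomato intermediate was set against the gate labelled negative CD150+, comparing a myeloid reporter gate with a MultiLin gate. The cell names of the Gfi1 gate also read CD150-, so the comparison sets a CD150- against a CD150+ sort, and that marker cannot be told apart from the reporters. Its direction again depends on labels whose order mean Gata1 messenger RNA did not follow. Myeloid genes were higher in the Gfi1 gate: Mpo by 7.96, Ctsg by 4.99 and Elane, neutrophil elastase, by 4.22, with Elane found in 54.8% against 8% of cells, or 42.9% against 4% at 10 TPM. Cd53 (chromosome 3, 106758861 to 106790149), a leukocyte tetraspanin, averaged 6.80 ± 3.53 against 0.64 ± 1.84 and was higher by 6.16. Megakaryocyte genes were lower, including F2r (-4.17), as were Gfi1b (-4.38), a repressor active in erythroid and megakaryocytic cells, and Gata2 (-3.99), a factor of stem and progenitor cells.

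The remaining highest genes were Lcp1 (4.60), Emb (4.47), Cd34 (4.21), which is also a gate gene, Atp8b4 (4.10) and Tyrobp (3.99). The remaining lowest were Vamp5 (-5.42), Mfsd2b (-5.00), Car2 (-4.67), Slc14a1 (-4.38), a urea transporter of red cells, Tuba8 (-4.02), Apoe (-3.83) and Smim5 (-3.76). Of 19 neutrophil genes 15 were higher and 0 lower, with scores of 2.78 ± 1.25 against 0.99 ± 0.99. Of 15 monocyte genes 11 were higher and 0 lower, with scores of 1.90 ± 1.42 against 0.47 ± 0.37, led by Ms4a6c (2.77), Lgals1 (2.74), Irf8 (2.19) and Psap (2.15). Of 17 megakaryocyte genes 13 were lower and 0 higher (-1.69), with the median member at percentile 0. On the erythroid list 9 of 18 were lower and 5 higher (-0.52), and Hba-a1 was among those higher, by 1.47. The S phase list (-1.32) and the G2 and M phase list (-1.14) had 15 of 15 members lower. Early lymphoid genes differed by 0.89 (5 of 12 higher, 1 lower), stem genes by -0.64, housekeeping by -0.45 (0.27 in cells matched on detected genes), basophil, mast and eosinophil genes by 0.37, B lineage by 0.24, dendritic by 0.20, interferon response by -0.15, immediate early and stress by 0.13 and T and innate lymphoid by 0.07.

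With the gate labelled intermediate-high as the reference in place of the gate labelled negative CD150+, the neutrophil difference was -0.02, the megakaryocyte difference -0.01, the erythroid difference 0.13 and the monocyte difference 0.89, and Ctsg was lower, at -1.90. As the log2 ratio of mean TPM the monocyte difference of 1.43 became 4.28, and in cells matched on detected genes the housekeeping difference was 0.27 and the immediate early and stress difference 1.23. Capture and gate cannot be told apart here either.

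The LSK DNDP gate was set against the equal-weight mean of the 6 other gates, to describe what marked this part of the LSK compartment. By its label the gate leaves out CD48-CD150+ cells, the fraction in which stem cells are commonly sorted. Stem cell genes were higher in it. Hlf (chromosome 11, 90336535 to 90390917), a transcription factor of blood stem cells, averaged 4.83 ± 3.53 against 0.42 and was found in 73.5% of LSK DNDP cells (61.4 to 83.5%). Car2 (chromosome 3, 14886269 to 14900770) was higher by 6.17. The interferon-inducible membrane proteins Ifitm1 (4.65) and Ifitm3 (4.18) were also higher. Mpo (-4.47) and Dntt (-4.55), the polymerase that adds nucleotides to receptor junctions, were lower, and Ctsg was listed at 0 in all 68 cells, which allows a share of up to 4.41%.

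Ly6a (3.64), a gate gene, Eltd1 (3.63), Lmo2 (3.42), Ube2l6 (3.38) and Cd63 (3.38) followed among the highest. Cd63 was above 5 of the 6 other gates, and the other highest genes named here were above all 6. The lowest also included Plac8 (-4.74), Gpr97 (-4.14), Cst7 (-3.17), Cks2 (-2.85), Clec12a (-2.76), Ctsg (-2.76) and Cd53 (-2.74). LSK DNDP cells lay above 3 of the 6 gates for Dntt and above 1 for Cd53. Of 18 stem genes 12 were higher and 0 lower, with a score of 2.63 ± 0.90 against 0.98 and the median member at percentile 100; Meis1 differed by 3.23. Of 12 early lymphoid genes 7 were lower and 1 higher (-1.07). The early lymphoid score, 1.47, was above the gates labelled negative CD150+ (0.81) and intermediate-high (1.01). It was below the gate labelled Gfi1-tdTomato intermediate (1.69) and the cKit+CD127+ (3.75), CLP Ly6D- (3.61) and CLP Ly6D+ (4.33) gates. Of 15 G2 and M phase genes 14 were lower and 0 higher (-0.84), with Birc5 (-1.35) and Top2a (-1.32) leading, while the S phase list differed by -0.41. Neutrophil genes went both ways (-0.44), with 8 of 19 lower and 4 higher, among them Gstm1 (1.74) and Csf3r (1.56). The neutrophil score, 0.89, was above the cKit+CD127+ (0.55), CLP Ly6D- (0.54) and CLP Ly6D+ (0.35) gates. It was below the gates labelled negative CD150+ (0.99), intermediate-high (2.79) and Gfi1-tdTomato intermediate (2.78).

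For the other lists, LSK DNDP cells differed by -0.52 for basophil, mast and eosinophil genes, 0.44 for erythroid (-0.70 as the log2 ratio of mean TPM), 0.40 for megakaryocyte, -0.38 for monocyte, 0.36 for housekeeping, -0.28 for B lineage, 0.16 for interferon response and -0.16 for T and innate lymphoid genes. The mean of the other gates joined unlike gates. The basophil, mast and eosinophil score, 0.43, was above the lymphoid gates (at most 0.15) and below the remaining gates. The megakaryocyte score, 1.47, was below the gate labelled negative CD150+ (2.60) and above the remaining gates. Dendritic (0.07) and immediate early and stress (0.08) scores had median members below 0, so that their signs differed. As log2 ratios of mean TPM, the early lymphoid difference became -2.19 and the neutrophil difference -1.41. The gate had a name prefix of its own, so capture and gate cannot be told apart.

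**Figure D3:**
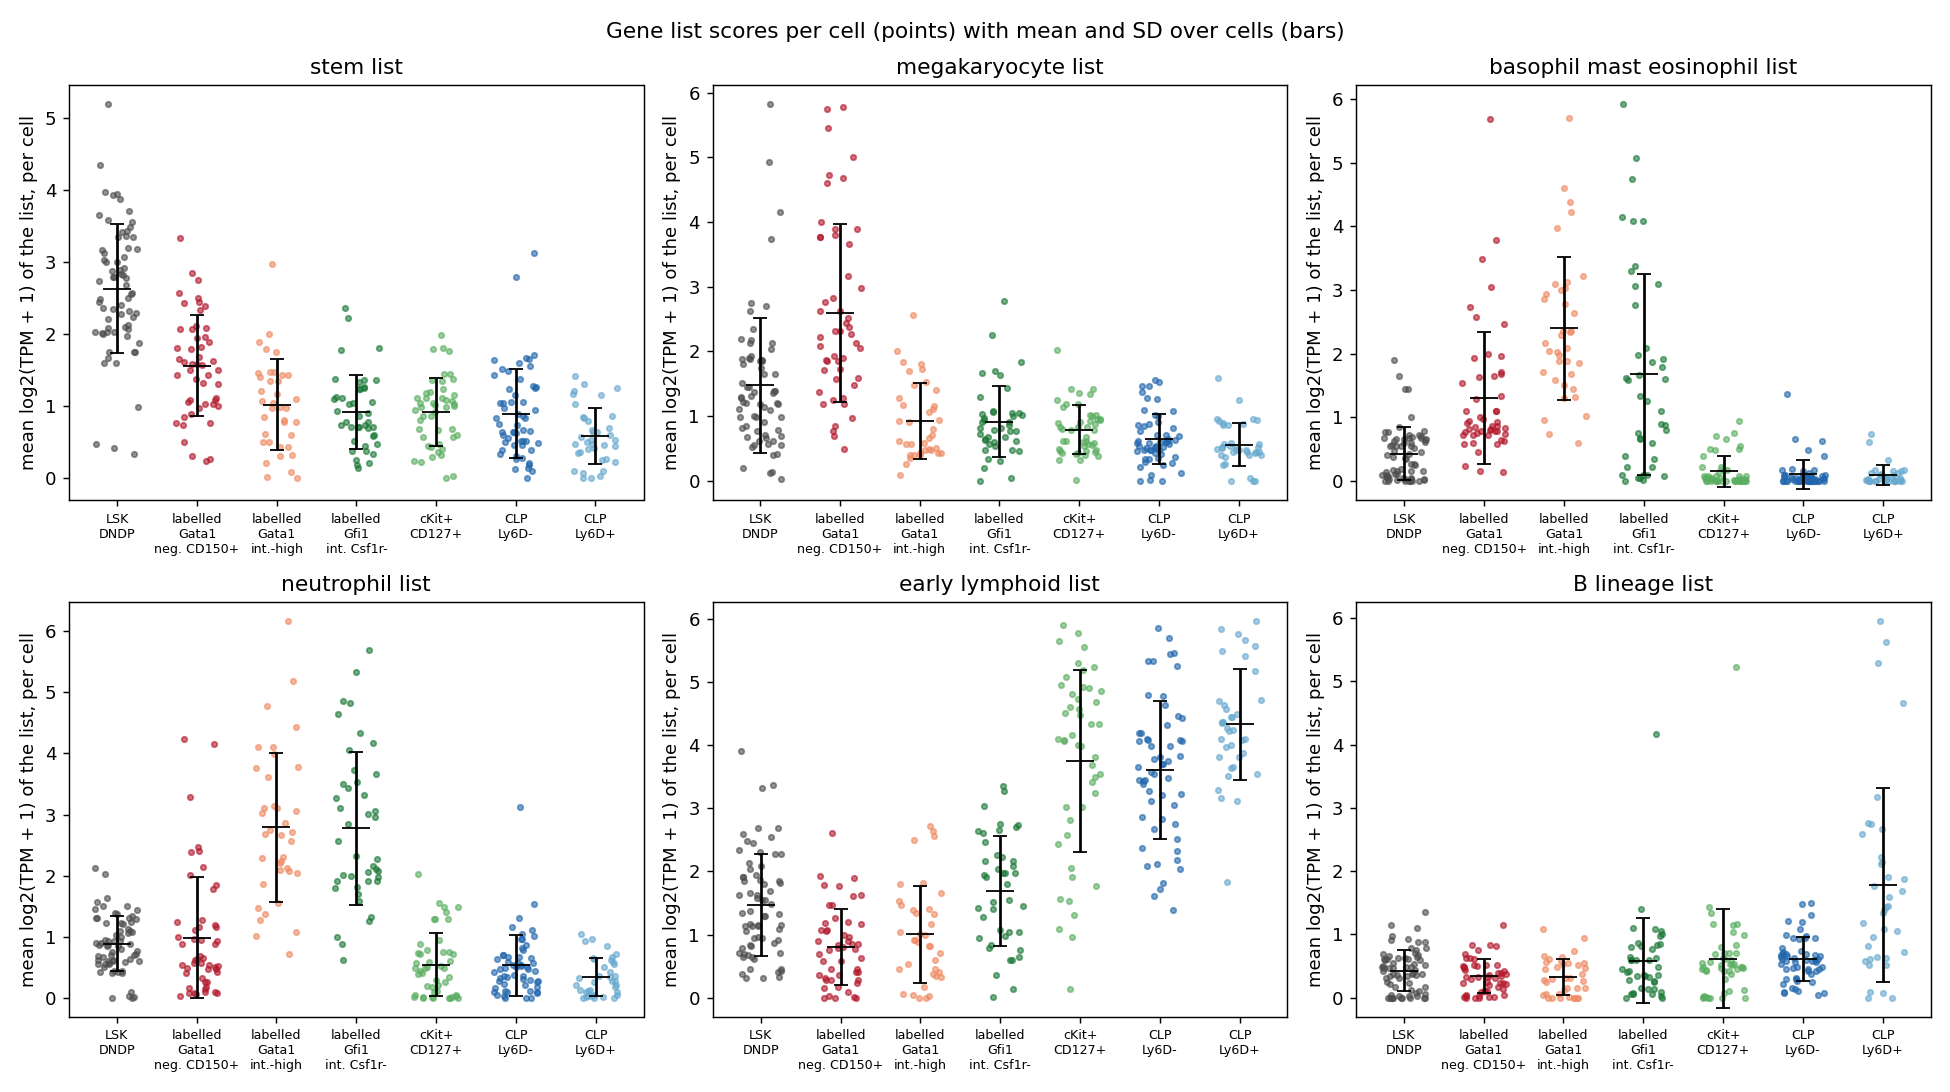
Each point is the mean log2(TPM + 1) over the measured genes of a list in 1 cell, by gate, for 6 lists, with the mean and the SD over cells as bars. The stem score was highest in LSK DNDP cells (2.63), the megakaryocyte score in the gate labelled negative CD150+ (2.60), and the B lineage score in CLP Ly6D+ cells (1.78). The neutrophil score was nearly equal in the gates labelled intermediate-high (2.79) and Gfi1-tdTomato intermediate (2.78), and lower in the other gates.

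Each gate was also set against the equal-weight mean of the other 6, and its 5 highest genes were named. In the gate labelled negative CD150+ they were Gata2 (5.72), Vamp5 (5.55), Mfsd2b (5.01), Apoe (4.74) and Tuba8 (4.32). In the gate labelled intermediate-high they were Cpa3 (6.95), Ctsg (6.71), Mpo (5.76), Prtn3 (4.61) and Rab44 (4.32). In the gate labelled Gfi1-tdTomato intermediate they were Mpo (6.24), Ctsg (4.49), Prtn3 (4.17), Elane (4.02) and Lgals1 (3.54). In the lymphoid gates Dntt came among the leading genes: 5.34 in cKit+CD127+ cells, followed by Dhrs3 (3.95), Lsp1 (3.92), Mn1 (3.39) and AW112010 (2.86); 7.04 in CLP Ly6D- cells, followed by Il12a (6.15), Cox6a2 (4.33), Flt3 (4.04) and Tsc22d1 (3.45); and 8.00 in CLP Ly6D+ cells, after Ly6d (8.20) and before Sdc4 (5.57), Il7r (5.05) and Blnk (4.39). The LSK DNDP genes included Car2, Ifitm1, Hlf and Ifitm3, with the values given above. Mpo was higher in the Gfi1 gate than in the gate labelled intermediate-high, Ctsg, Prtn3 and Lgals1 the reverse, and Dntt was highest in CLP Ly6D+ cells.

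Co-detection of genes of different lineages in the same cell was counted for 14 fixed pairs, beside the number expected from the product of the shares. Lymphoid and myeloid genes were found together in the lymphoid gates. Dntt was found in 55 of 56 CLP Ly6D- and 37 of 37 CLP Ly6D+ cells, and Flt3 in 51 of the CLP Ly6D- cells, so that their counts with Mpo there could hardly differ from the expected ones. Dntt and Mpo were found together in 28 of 56 CLP Ly6D- cells (27.5 expected) and 22 of 47 cKit+CD127+ cells (19.7 expected). Flt3 and Mpo were found together in 21 of 47 cKit+CD127+ cells (16.9 expected) and 25 of 56 CLP Ly6D- cells (25.5 expected), and Il7r and Mpo in 21 of 56 CLP Ly6D- cells (17.5 expected). In cKit+CD127+ cells, where fewer cells held the lymphoid gene, the counts were above the expected ones. At 10 TPM they were 19 for Flt3 and Mpo (14.7 expected) and 21 for Dntt and Mpo (17 expected). All 22 cells with Mpo held Dntt, so that count could not be higher. The expected numbers, here and for all pairs, take no account of the detected genes per cell, which ranged from 276 to 3920 in this gate.

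In the MultiLin gates, Gata1 and Mpo were found together in 14 of 50 cells (11.8 expected) of the gate labelled negative CD150+ and 13 of 37 cells (13.2 expected) of the gate labelled intermediate-high. At 10 TPM these counts were 5 (4 expected) and 7 (8.03 expected). Pf4 and Mpo were found together in 8 (9.5 expected) and 10 (9.46 expected) cells, and at 10 TPM in 2 (3.04 expected) and 2 (2.68 expected). Gata2 and Gata1 were found together in 30 of 50 (29.8 expected) and 14 of 37 cells (11 expected), and Gata1 and Cebpa in 3 (2.48 expected) and 7 (7.19 expected). Mpo was found in 35 of 37 cells of the gate labelled intermediate-high and Gata2 in 48 of 50 cells of the gate labelled negative CD150+, so that the counts with them there could hardly differ from the expected ones. Gata1 and Gfi1 were found together in 0 of 337 cells, which allows a share of up to 0.89% over all gates pooled. The expected number was at most 1.51 in any gate, so that a count of 0 says little. Gfi1 was found in 0 of 50 cells labelled negative CD150+, and Gata1 in 0 of 56 CLP Ly6D- and 0 of 37 CLP Ly6D+ cells. The count with both genes could only be 0 in these gates. In LSK DNDP cells, Procr and Flt3 were found together in 6 of 68 (4.53 expected) and Mecom and Flt3 in 8 (8.65 expected). The remaining pairs were rare: Irf8 and Gfi1, and Ebf1 and Mpo, reached at most 3 cells in any gate, Irf8 and Cebpe 2, and Ebf1 and Gata3 1.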

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

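The removal of cells in which few genes held most of the TPM, and the matching of cells on genes listed above 0, were chosen after the results were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the numbers in the labels count cells within a gate and pair nothing across gates, and no animal is named. Across the alternatives other than a change of reference gate, 690 list differences were recomputed and 36 took the opposite sign. The largest of these in the main calculation was the G2 and M phase difference between the MultiLin gates, which turned from -0.84 to 0.15 in cells matched on genes listed above 0. Next came the housekeeping difference of the Gfi1 gate, from -0.45 to 0.27 in cells matched on detected genes, and the erythroid difference of LSK DNDP cells, from 0.44 to -0.70 as the log2 ratio of mean TPM. Under the same alternatives, again without a change of reference gate, a subset of 15 list differences was recomputed 137 times, with 0 of opposite sign. This subset was not named in the plan fixed beforehand and leaves out the differences just described as turning. The 0 therefore holds for a selected subset. The B lineage difference ranged from 0.74 to 3.49, the megakaryocyte difference between the MultiLin gates from -2.95 to -0.98, the neutrophil difference there from 1.11 to 2.49, the interferon response difference from 0.39 to 1.70 and the stem difference of LSK DNDP cells from 0.99 to 2.37. The Gata1 share in the gate labelled intermediate-high minus that in the gate labelled negative CD150+ ranged from -25.7 to -18.6 percentage points.

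As the log2 ratio of mean TPM, which a few cells with high values can set, 5 of these list differences moved by more than 1 SD over cells: B lineage to 3.49, megakaryocyte between the MultiLin gates to -2.95, monocyte in the gate labelled Gfi1-tdTomato intermediate to 4.28, and early lymphoid and neutrophil in LSK DNDP cells to -2.19 and -1.41. With the gate labelled intermediate-high as the reference for the Gfi1 gate, the erythroid difference moved to 0.13, the megakaryocyte difference to -0.0110, the neutrophil difference reversed to -0.0151 and Ctsg reversed to -1.90, since another gate was then compared. Of 960 recomputed differences of named genes, 943 stayed within 1 SD over cells, 16 moved further and 1 reversed. That SD often exceeded the difference itself, so staying within it was a weak bound. For Edf1 in cKit+CD127+ against CLP Ly6D- cells, for example, the difference was 2.89 and the SDs were 3.74 and 3.08. Of the recomputed shares, 757 stayed within their interval and 146 did not. Of the named genes, 20 of 20 per comparison were kept under both other filters, and at least 4 of 5 per gate with a pseudocount of 0.1. In cells matched on detected genes, the S phase and the G2 and M phase differences between the MultiLin gates went from -1.04 and -0.84 to -0.04 and -0.08; the cause was not tested. Leaving out cells with under 1000 detected genes removed 1 cell, cell 76 of the cKit+CD127+ gate. Depth was unknown, and gates of 37 cells leave a share of 0 open up to 8.11%.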

Other observations

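The test of exchanged labels, the test of mature neutrophil RNA in Cxcr2, the comparison of low values by the start of the cell name (added after the Cxcr2 tests were run), the matching on genes listed above 0, and the genes and 15 co-detection pairs from which the next paragraphs draw were chosen after the results were seen; the others were written down before.

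The gate labelled Gfi1-tdTomato intermediate held cells with genes of several myeloid fates. F13a1, a coagulation factor subunit of monocytes, was found in 15 of 42 cells and Ccr2, the receptor that guides monocytes, in 12 of 42, against 0 cells in each MultiLin gate and at most 4 in any other gate. Cpa3 was found in 24 of 42 cells and Ms4a2, a chain of the IgE receptor, in 12 of 42, with 11 cells holding both (6.86 expected from the product of shares). Cpa3 and Irf8 were found together in 4 cells (8.57 expected), and Cpa3 and F13a1 in 6 (8.57 expected), while Elane and F13a1 shared 10 cells (8.21 expected). Cpa3 and Elane shared 13 (13.1 expected), Elane and Irf8 7 (8.21 expected), Elane and Ms4a2 6 (6.57 expected) and Irf8 and F13a1 6 (5.36 expected). At 10 TPM, Cpa3 and Irf8 shared 3 cells (6.57 expected), Cpa3 and F13a1 3 (5.48 expected), Cpa3 and Ms4a2 11 (6.57 expected), Cpa3 and Elane 8 (9.86 expected) and Elane and Ms4a2 4 (5.14 expected). Elane and Irf8 then lay above the expected number, with 7 cells (5.14 expected), as did Irf8 and F13a1 with 5 (2.86 expected) and Elane and F13a1 with 7 (4.29 expected).

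In LSK DNDP cells, Hlf and Flt3 were found together in 27 of 68 cells (20.6 expected), and in 23 at 10 TPM (15.2 expected). In CLP Ly6D+ cells, Rag1 and Ebf1, a factor that specifies B cells, shared 6 of 37 cells (3.41 expected), and 4 at 10 TPM (2.65 expected). In the gate labelled negative CD150+, Ctsg and Pf4 shared 3 of 50 cells (6.5 expected), and 0 at 10 TPM (1.9 expected), and Cpa3 and Pf4 shared 9 (10 expected), and 2 at 10 TPM (4.94 expected). In the gate labelled intermediate-high, Ctsg was found in 37 of 37 and Cpa3 in 34 of 37 cells, so that their counts with Pf4 (10 and 10) could hardly differ from the expected ones. At 10 TPM, Ctsg and Pf4 shared 2 cells there (2.51 expected) and Cpa3 and Pf4 3 (2.68 expected), with Pf4 in only 3 cells. In LSK DNDP cells the antigen presentation genes H2-Aa and Cd74 were found in 22.1% and 25% of cells; in the other gates the shares were at most 8.51% for H2-Aa and 17% for Cd74, both in cKit+CD127+ cells.

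Gata1 and megakaryocyte genes were lower in the gate labelled Gata1-mCherry intermediate-high than in the gate labelled negative CD150+, against the reporter label. A difference in detected genes could account for part: in matched cells the megakaryocyte difference was -1.06, or 63.4% of the -1.68 in all cells, between the bounds set for and against this explanation. Matching on genes listed above 0 was chosen after the main differences were seen, and was run before the planned matching. It gave -1.25 (74.7%), just short of the bound against the explanation. The planned count at 1 TPM follows the detection threshold fixed beforehand, and under both the explanation stays open. Exchanged gate labels could also give the pattern; Slamf1, the gene of CD150, was found in 4% of cells of the gate labelled CD150+ (0.49 to 13.7%) and 0 of 37 of the other, too few to decide. A reporter protein that does not follow the messenger RNA, and megakaryocyte-biased cells selected by CD150, were not tested.

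Transcripts of neutrophil granules lay at low level in the MultiLin and LK gates: Camp was found in 42% of the gate labelled negative CD150+, 56.8% of the gate labelled intermediate-high and 54.8% of the gate labelled Gfi1-tdTomato intermediate, with medians of 3.63, 5.66 and 9.03 TPM where listed, in 3 of 68 LSK DNDP cells and in 0 cells of the cKit+CD127+ and CLP gates; S100a8 and S100a9 were also found in 33.8% and 26.5% of LSK DNDP cells. RNA from other cells carried into the captures may be a source, and would put these transcripts in cells with and without Elane alike. The mean ratio of observed to expected cells with both was 0.99 in the gate labelled intermediate-high and 1.08 in the gate labelled Gfi1-tdTomato intermediate. In the gate labelled negative CD150+ it was 1.87, the highest of the 3, but from 4 Elane cells. Ratios near 1 are those that carried RNA would give, but the bound set beforehand asked for them in each of the 3 gates. In the gate labelled negative CD150+ the 4 Elane cells were too few to decide. Carried RNA and low expression in the cells themselves therefore cannot be told apart.

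Cxcr2 (chromosome 1, 74153994 to 74161246), a chemokine receptor of mature neutrophils, reached 1 TPM in 332 of 337 cells, with a median of 46.4 TPM and gate means from 5.06 to 5.90. Mature neutrophils or their RNA are argued against in the CLP gates, where Cxcr2 was found in 97.8% of cells and the highest share of another such marker was 1.08%. Reads that do not come from a cell-specific transcript could vary little between cells; the SD of Cxcr2, 1.65, was at percentile 5 of the 200 genes nearest in mean, at the bound set beforehand and not below it, so this stays open. No other explanation, biological ones included, was tested.

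Values under 10 TPM of genes abundant in another gate were compared with the starts of the cell names. Their share was 1.06, 1.52, 1.38 and 2.28 times as high for genes of the gate with the same start as for the highest other gate, in the gates labelled negative CD150+ and intermediate-high and in the CLP Ly6D- and CLP Ly6D+ gates, the last from 6 genes. Such a difference was also found without a shared start: in the gate labelled Gfi1-tdTomato intermediate the share was 14.2% for genes of the cKit+CD127+ gate and 8.45% for the next gate. Ly6d had a median of 1.91 TPM where listed in CLP Ly6D- cells and 2091 TPM in CLP Ly6D+ cells. Poldip3 had a median of 1.08 TPM where listed in the gate labelled intermediate-high and 526.7 TPM in the gate labelled negative CD150+. Lepr was found in 285 of 337 cells, with Col1a1 in 0.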
